A study of Mus musculus with 4 samples.

How the data were processed

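Poly(A) RNA of CD8+ T cells enriched from tumour grafts was sequenced on a DNBSEQ-G50 instrument, per the labels' protocols, after selection with oligo-coated beads. The deposited files hold 1 column of values per library for 36464 Ensembl gene IDs, and the unit is not named in them. The deposited values are read here as RPKM, computed by the authors, because a value multiplied by the exon length of its gene in GENCODE release M21 was a whole multiple of a single step per library. Within a tolerance of 0.02, this held for 98.95%, 98.97%, 98.95% and 98.92% of the genes with under 1000 reads in IgG replicate 1, IgG replicate 2, anti-SIGLEC15 replicate 1 and anti-SIGLEC15 replicate 2. Whether reads or fragments were counted is not stated. The builds named are GRCm38 and mm10, per the submitters' processing notes; the aligner, the counting tool and the annotation release are not given in the sources used here.

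The step of each library gave its total of counted reads, between 14854802 and 16026197. Symbols and coordinates were taken from GENCODE M21 on GRCm38 for 36346 IDs, and 118 IDs had no symbol. A further 19 IDs that shared a symbol with another ID were kept apart from the symbol. Reads of mitochondrially encoded genes made up 11.88% and 12.96% of counted reads in the IgG libraries and 8.92% and 18.38% in the anti-SIGLEC15 libraries.

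Libraries were grouped by the treatment in their titles, with 2 per group. Each library mixed 3 samples, so an SD or p describes the spread between pools and not between mice. The test had been planned for counts with a fallback for normalized values, and the fallback was used: limma with an intensity trend and robust variance shrinkage on log2(RPKM + 1), for the 12484 genes with at least 1 RPKM in at least 2 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of genes with low values. Gene lists, 34 in number, covered T cell states, pathways and the markers of other cell types, and were fixed before the data were examined. The 25 lists with at least 5 tested members were tested with camera, two-sided, at a preset correlation of 0.01, and again with an estimated correlation and with fry. A median log2 fold change is given for each list, and the test is against all other genes, so that its direction can differ from the sign of the median.

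The named genes followed a rule set before the data were examined. It takes genes past the threshold with a mean of at least 5 RPKM. Both anti-SIGLEC15 libraries must lie on the same side of both IgG libraries. Where no gene qualifies, the rule takes the 5 higher and 5 lower genes with the smallest p. These need the same mean, without the condition on sides. The rule leaves out predicted models, pseudogenes and receptor segments. It also names Siglec15, Cd8a, Cd4, Cd3e, Gzmb, Prf1, Ifng, Pdcd1, Tox, Tcf7 and Mki67. Other genes were named as examples of lists after their values were seen, and the text says so.

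Alternatives were median-of-ratios, upper-quartile and T cell list scaling, no filter, a filter at 5 RPKM, a pseudocount of 0.1, limma-voom on the recovered reads (at least 10 reads), a test against a 1.5-fold change, a replicate block, and each library left out in turn. A fit with the T cell identity level as a covariate, array weights and protein-coding genes alone were added after the data were seen. With a library left out, the lone library of its group was assumed to vary like the other group.

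The test was tested on simulated reads for the comparison of anti-SIGLEC15 against IgG, with 200 genes changed in each of 5 draws. With the spread of the real libraries (12424 genes tested on average), it recovered 0% of 2-fold, 4.4% of 4-fold, 46.4% of 8-fold and 66% of 16-fold changes, with 6.1% of calls false. With a dispersion of 0.05 in every gene (12515 genes), it recovered 18%, 96%, 100% and 99.6%, with 13.8% of calls false, above the nominal level. In draws without any change, camera called 0 lists. The simulated genes varied independently of each other, so this does not test camera on correlated genes. The versions were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.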

Results

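Gene expression was measured by RNA sequencing in CD8+ T cells, the killer lymphocytes that recognise tumour cells, enriched from percutaneous tumour grafts in male C57BL/6 mice. Mice received control IgG or an antibody against SIGLEC15, a lectin that binds sialic acids and has been studied as an immune checkpoint molecule, by intraperitoneal injection over 2 weeks. Each treatment had 6 mice, and the grafts were collected on day 19. Each library was made from a mixture of 3 cell pellets, which gave 2 libraries per treatment. The comparison of the 2 treatments asks how the function of CD8+ T cells in the tumour changes when SIGLEC15 is blocked, as the title of the study states. The reads counted in genes, recovered from the deposited RPKM values, numbered 16026197 in IgG replicate 1, 15512090 in IgG replicate 2, 15696667 in anti-SIGLEC15 replicate 1 and 14854802 in anti-SIGLEC15 replicate 2. The number of genes with a value above 0 lay between 24309 and 26722 per library.

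The transcript of the target, Siglec15 (ENSMUSG00000091055, minus strand of chromosome 18, 78043614 to 78057395 in GRCm38), had 0 reads in all 4 libraries. A count of 3 reads would correspond to 0.162 RPKM in IgG replicate 1, 0.167 RPKM in IgG replicate 2, 0.165 RPKM in anti-SIGLEC15 replicate 1 and 0.175 RPKM in anti-SIGLEC15 replicate 2, so expression of Siglec15 in these cells was not detectable at this depth. This limit covers counting error only.

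Transcripts of a cluster of granzymes, the serine proteases of killer cell granules, lay lower in both anti-SIGLEC15 libraries than in both IgG libraries. Gzmd (ENSMUSG00000059256, chromosome 14, 56129556 to 56132608) measured 175 ± 41.0 RPKM (SD, n = 2) with IgG and 55.8 ± 9.49 RPKM (SD, n = 2) with anti-SIGLEC15. Its neighbour Gzme (ENSMUSG00000022156, chromosome 14, 56117626 to 56120625) measured 139 ± 30.6 RPKM and 42.4 ± 9.72 RPKM. Haemoglobin transcripts, which are made in red cells, were lower by a larger factor: Hbb-bs went from 673 ± 443 RPKM with IgG to 31.6 ± 31.2 RPKM with anti-SIGLEC15, and Hba-a1 from 445 ± 280 RPKM to 23.1 ± 24.0 RPKM. The heat shock protein genes Hspa1a and Hspa1b and Klrg1, a receptor of differentiated effector T cells, lay higher with anti-SIGLEC15. Hspa1a and Hspa1b belong to the list of immediate early and dissociation stress genes, called immediate early genes below. In that list 2 of 22 tested members lay higher in both anti-SIGLEC15 libraries. No gene passed the test: limma on log2(RPKM + 1) called 0 of 12484 genes at a Benjamini-Hochberg adjusted p of 0.05, with 146 genes (1.17%) at an unadjusted p under 0.05. A second fit, limma-voom on the recovered reads, called 0 of 15061 genes, with 90 at an unadjusted p under 0.05. The call depends on single libraries: genes were called only in the fits that left out an IgG library. In those fits the spread comes from the anti-SIGLEC15 pair alone, which correlated at 0.972 on the log2 scale. Without an anti-SIGLEC15 library it comes from the IgG pair, which correlated at 0.884. The contrast between these fits can therefore follow from which pair gives the spread. With 2 libraries against 2, the smallest two-sided permutation p is 0.333.

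The log2 fold change on the log2(RPKM + 1) scale was -1.62 (SE 0.30) for Gzmd and -1.69 (SE 0.32) for Gzme, each with an adjusted p of 1 in limma. It was -4.42 (SE 0.69) for Hbb-bt, -4.64 (SE 0.92) for Hbb-bs and -4.54 (SE 0.95) for Hba-a1. On the other side, it was 1.61 (SE 0.37) for Klrg1, from 3.77 ± 1.96 RPKM with IgG to 13.0 ± 0.902 RPKM with anti-SIGLEC15, 1.17 (SE 0.26) for Hspa1a and 1.15 (SE 0.27) for Hspa1b. The short transcripts Mir7671 and Snord118 had log2 fold changes of 1.43 (SE 0.43) and 1.09 (SE 0.34), and genes this short reach 5 RPKM with few reads. When the libraries were scaled to the T cell identity genes, the log2 fold changes were 1.06 for Klrg1, 0.52 for Hspa1a, 0.49 for Hspa1b, 0.85 for Mir7671 and 0.51 for Snord118. These were the 5 higher and 5 lower genes with the smallest p above 5 RPKM, and the adjusted p of each was 1. Hspa1a and Hspa1b are near-identical copies, as are the paired alpha and the paired beta globin genes, and Gzmd, Gzme and Gzmg are close relatives, so reads can be shared within each of these families. Of all tested genes, 1511 (12.1%) lay higher and 752 (6.02%) lower in both anti-SIGLEC15 libraries than in both IgG libraries, where chance gives 16.7% in each direction.

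**Figure D1:**
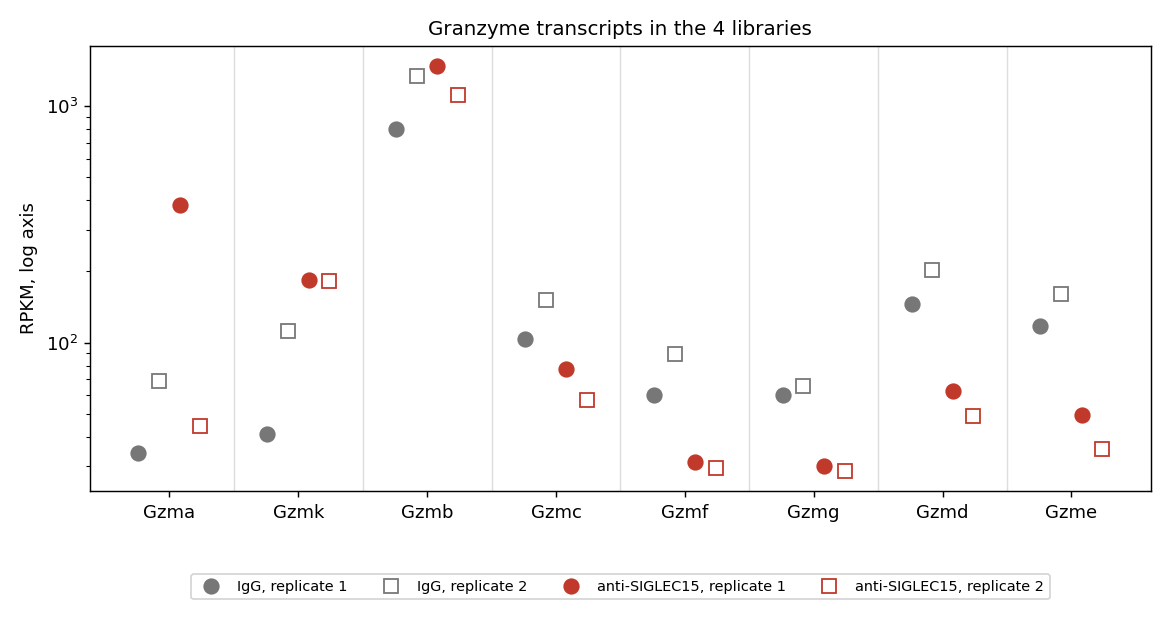
Granzyme transcripts in each of the 4 libraries, as RPKM on a log axis, with a point per library (grey, IgG; red, anti-SIGLEC15; filled circle, replicate 1; open square, replicate 2). Gzmc, Gzmf, Gzmg, Gzmd and Gzme lay lower and Gzmk higher in both anti-SIGLEC15 libraries, while Gzmb and Gzma overlapped between the treatments, and no gene passed the test over all genes.

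Among the genes for cytotoxic effector functions, the members did not move together. Of 25 tested members, 8 lay higher and 4 lower in both anti-SIGLEC15 libraries. The 4 lower members were Gzmc, Gzmd, Gzme and Gzmf, and the higher ones included the chemokine genes Ccl5 (1148 ± 999 RPKM with IgG, 2557 ± 631 RPKM with anti-SIGLEC15, SD, n = 2) and Ccl4, Gzmk (76.2 ± 49.9 and 183 ± 1.40 RPKM) and the interferon gamma gene Ifng (115 ± 78.6 and 177 ± 3.90 RPKM). The log2 fold change of Ifng was 0.81, but 0.06 without IgG replicate 1, 1.56 without IgG replicate 2 and 0.15 when scaled to the T cell identity genes. Gzmb, the most abundant granzyme, measured 1067 ± 378 RPKM with IgG and 1294 ± 254 RPKM with anti-SIGLEC15, and the perforin gene Prf1 191 ± 126 and 145 ± 12.5 RPKM. The list of cytotoxic genes as a whole rose by a median log2 fold change of 0.56, with an adjusted p of 0.0466 in camera, and the adjusted p was 0.873 with an estimated correlation. Adjusted over the list alone, 2 members passed, Gzmd and Gzme, and both were lower, opposite to the list. Without IgG replicate 1 the median was -0.02 and the list passed as lowered, and without anti-SIGLEC15 replicate 2 the call ended (adjusted p = 0.303, in a range from 8.62e-09 to 0.952 over the alternatives). It also ended under median-of-ratios and upper-quartile scaling, with no filter, with a filter at 5 RPKM and with fry. With members shared with other lists removed (adjusted p = 0.899) and with the T cell level as covariate (adjusted p = 0.0861), the call ended and the test pointed down. Genes of this list other than Gzmb, Prf1, Ifng, Gzmd and Gzme were chosen after their values were seen.

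Genes that mark T cells and the CD8 lineage rose as lists, and the rise depended on IgG replicate 1. The geometric mean of RPKM + 1, less 1, over the T cell identity genes was 24.7 in IgG replicate 1, 69.3 in IgG replicate 2 and 64.7 in each anti-SIGLEC15 library. For the CD8 lineage genes it was 66.1, 203, 193 and 203. Cd8a, which encodes a chain of the CD8 coreceptor, measured 115 RPKM in IgG replicate 1, 351 RPKM in IgG replicate 2, and 290 and 315 RPKM in the anti-SIGLEC15 libraries. Cd3e, part of the T cell receptor complex, measured 11.03, 35.9, 31.4 and 30.2 RPKM in the same order. The median log2 fold change was 0.59 for T cell identity (camera, adjusted p = 5.85e-07) and 0.57 for the CD8 lineage (adjusted p = 1.33e-05), and both calls were lost with an estimated correlation (adjusted p = 0.691 for each). In each of these lists, 3 members lay higher in both anti-SIGLEC15 libraries, among 23 tested T cell identity genes and 12 tested CD8 lineage genes. Without IgG replicate 1 the medians were -0.09 and -0.16, so the direction turned. Over the alternatives tried, the adjusted p of the T cell identity list ran from 3.04e-18 to 0.952.

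**Figure D2:**
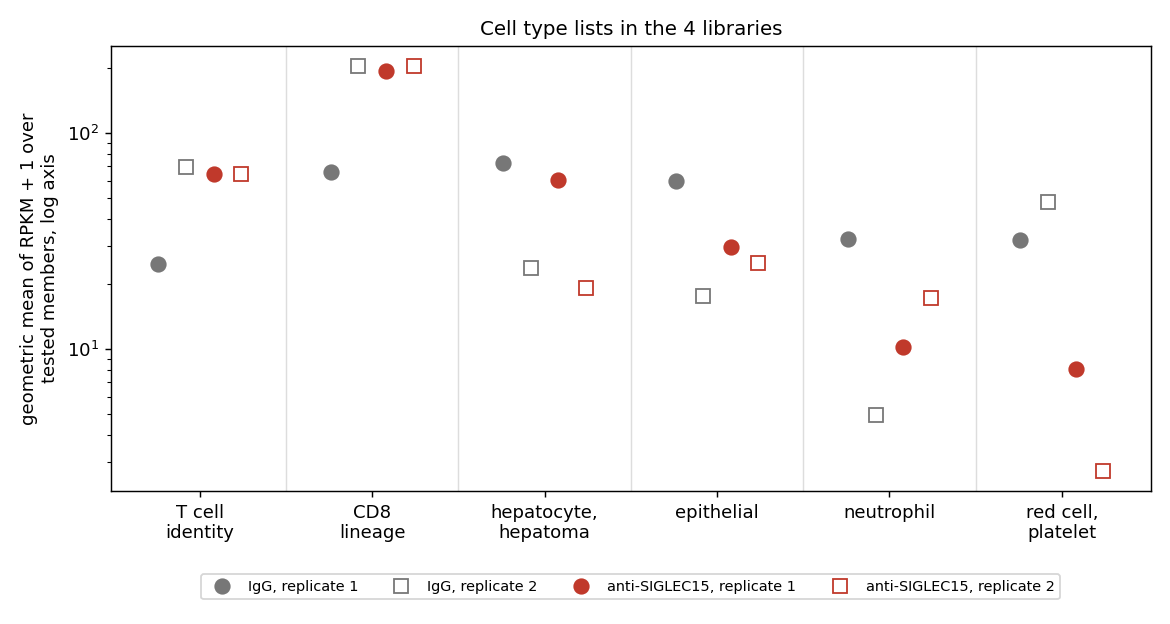
Levels of 6 cell type lists in each of the 4 libraries, as the geometric mean of RPKM + 1, less 1, over the tested members on a log axis, with a point per library. IgG replicate 1 had the lowest T cell identity (24.7) and CD8 lineage (66.1) levels and the highest hepatocyte (72.5), epithelial (59.9) and neutrophil (32.1) levels, and the red cell and platelet list was lower in both anti-SIGLEC15 libraries.

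Genes of hepatocytes and hepatoma cells were abundant in these CD8-enriched libraries. Of the 14 tested members, 8 were highest in IgG replicate 1 and 6 in anti-SIGLEC15 replicate 1, and the geometric means of RPKM + 1, less 1, of the list in these libraries were 72.5 and 60.6, against 23.6 in IgG replicate 2 and 19.2 in anti-SIGLEC15 replicate 2. Alb, which encodes serum albumin, measured 2795 RPKM in IgG replicate 1, 556 RPKM in IgG replicate 2, and 1089 and 625 RPKM in the anti-SIGLEC15 libraries. Afp, the alpha-fetoprotein gene expressed by fetal liver and by liver tumours, measured 1049, 210, 482 and 216 RPKM in the same order. The apolipoprotein gene Apoa1, picked after its values were seen, measured 64.42, 18.78, 92.16 and 16.72 RPKM. The line of the grafted tumour is not given in the labels. The hepatocyte list (median log2 fold change -0.33, camera adjusted p = 0.158, 14 tested members) and the epithelial list (-0.43, adjusted p = 0.315, 9 tested members) did not pass, and 0 of their members lay apart between the treatments in either direction. With the replicate block, the hepatocyte list was called as lowered. The neutrophil genes followed neither treatment: S100a9, a calcium-binding protein of neutrophils, measured 579 RPKM in IgG replicate 1, 46.7 RPKM in IgG replicate 2, and 149 and 245 RPKM in the anti-SIGLEC15 libraries. The neutrophil list did not pass either (median 0.10 with a downward test, adjusted p = 0.571). Without IgG replicate 1, the medians of these lists were 0.53 for hepatocytes, 0.68 for epithelial cells and 1.46 for neutrophils. Without IgG replicate 2 they were -1.16, -1.61 and -1.06, so the direction depended on which IgG library was kept.

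Exhaustion and activation genes also had IgG replicate 1 as their lowest library, with geometric means of RPKM + 1, less 1, of 11.6, 30.5, 26 and 27.1 for exhaustion and 13.3, 25.9, 24.4 and 26.1 for activation in IgG replicates 1 and 2 and anti-SIGLEC15 replicates 1 and 2. The exhaustion and checkpoint list rose by a median of 0.44 (camera, adjusted p = 7.43e-05; adjusted p = 0.734 with an estimated correlation), but 0 of its 24 tested members lay higher or lower in both anti-SIGLEC15 libraries. Pdcd1, which encodes the inhibitory receptor PD-1, measured 177 ± 118 RPKM with IgG and 209 ± 52.7 RPKM with anti-SIGLEC15 (SD, n = 2). Tox, a transcription factor of exhausted T cells, measured 19.04 ± 15.7 and 21.02 ± 0.331 RPKM. Without IgG replicate 1, the exhaustion list turned and fell, with a median of -0.23. The activation and costimulation list rose by a median of 0.38 (adjusted p = 0.000644; adjusted p = 0.691 with an estimated correlation), with 4 of 19 tested members higher in both anti-SIGLEC15 libraries, and its median was -0.15 without IgG replicate 1. Its adjusted p was 0.116 without anti-SIGLEC15 replicate 2, in a range from 3.45e-06 to 0.971 over the alternatives. These 4 were Tnfsf14, which encodes the costimulatory ligand LIGHT, Nfkbid, the early activation marker Cd69 and Irf4, chosen after their values were seen. The proliferation marker Mki67 measured 25.6 ± 8.69 and 35.1 ± 9.82 RPKM, Cd4 3.47 ± 2.02 and 5.74 ± 1.53 RPKM, and Tcf7, a transcription factor of stem-like T cells, 17.4 ± 11.3 and 18.5 ± 12.1 RPKM. In limma, the adjusted p of Cd8a, Cd3e, Pdcd1, Tox, Gzmb, Prf1, Ifng, Mki67, Cd4 and Tcf7 was 1.

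Interferon-stimulated genes rose as a list by a median of 0.36 (camera, adjusted p = 7.61e-05; adjusted p = 0.691 with an estimated correlation), with 12 of 33 tested members higher and 0 lower in both anti-SIGLEC15 libraries. The geometric mean of RPKM + 1, less 1, of this list was 6.61 in IgG replicate 1 and 5.63 in IgG replicate 2. It was 9.34 in anti-SIGLEC15 replicate 1 but 6.56 in anti-SIGLEC15 replicate 2, no higher than in IgG replicate 1. Irf7, a transcription factor of the type I interferon response, measured 10.2 ± 2.98 RPKM with IgG and 21.1 ± 6.44 RPKM with anti-SIGLEC15 (SD, n = 2), and the antiviral enzyme gene Oas1a 3.67 ± 0.153 and 6.76 ± 1.28 RPKM. The adjusted p of the interferon list was 2.67e-07 without IgG replicate 1 (median 0.31) and 0.325 without IgG replicate 2, in a range from 3.44e-08 to 0.952 over the alternatives. The MHC class I antigen presentation list rose by a median of 0.30 (adjusted p = 0.000288; adjusted p = 0.691 with an estimated correlation), with 9 of 18 tested members higher and 1, the peptidase gene Erap1, lower in both anti-SIGLEC15 libraries. H2-Q4 measured 124 ± 40.9 and 222 ± 34.0 RPKM and H2-Q6 248 ± 184 and 518 ± 83.6 RPKM, and these class I genes resemble each other closely enough to share reads. Without IgG replicate 1 the median of the MHC class I list was 0.07 and its call ended. Irf7, Oas1a, Erap1 and the H2-Q genes were chosen after their values were seen.

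Genes of homing and tissue residency rose by a median of 0.82 (camera, adjusted p = 3.93e-09; adjusted p = 0.691 with an estimated correlation), with 9 of 16 tested members higher and 0 lower in both anti-SIGLEC15 libraries. Cxcr3, a chemokine receptor of effector T cells, measured 4.08 ± 3.98 RPKM with IgG and 16.7 ± 4.94 RPKM with anti-SIGLEC15 (SD, n = 2), Ccr2 3.65 ± 2.49 and 9.73 ± 0.503 RPKM, and the integrin gene Itgb7 20.9 ± 11.9 and 51.1 ± 26.3 RPKM. These 3 genes share IgG replicate 1 as their lowest library, and without it the median of the list was 0.13 and the adjusted p 0.108, in a range from 6.54e-14 to 0.952 over the alternatives. The naive, memory and stem-like list rose by a median of 0.44 (adjusted p = 0.00125; adjusted p = 0.691 with an estimated correlation), with 6 of 19 tested members higher in both anti-SIGLEC15 libraries, among them Il7r, the interleukin 7 receptor gene (3.34 ± 2.13 and 7.41 ± 1.95 RPKM), and S1pr1, which guides T cells out of tissue (3.04 ± 2.35 and 8.70 ± 4.995 RPKM). The geometric mean of RPKM + 1, less 1, of this list was 7.96 and 8.22 in IgG replicates 1 and 2. In anti-SIGLEC15 replicates 1 and 2 the list had 12.2 and 8.74. Its median was 0.23 without IgG replicate 1, and its call ended without IgG replicate 2 (adjusted p = 0.154, in a range from 0.000189 to 0.952 over the alternatives) and with a filter at 5 RPKM. The genes named here were chosen after their values were seen.

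Glycolysis genes fell as a list by a median of -0.27 (camera, adjusted p = 3.51e-05; adjusted p = 0.498 with an estimated correlation), with 8 of 18 tested members lower and 0 higher in both anti-SIGLEC15 libraries. Tpi1, the triosephosphate isomerase gene, measured 341 ± 6.14 RPKM with IgG and 257 ± 22.6 RPKM with anti-SIGLEC15 (SD, n = 2), Pgk1 453 ± 28.7 and 356 ± 20.4 RPKM, and Ldha 641 ± 51.0 and 518 ± 41.4 RPKM. The median of the glycolysis list was -0.24 without IgG replicate 1 and -0.28 without IgG replicate 2 (adjusted p = 0.0548, in a range from 1.48e-06 to 0.622 over the alternatives). The hypoxia response list also fell, by a median of -0.48 (adjusted p = 7.43e-05; adjusted p = 0.691 with an estimated correlation), but 2 of its 15 tested members, Pdk1 and Ero1l, lay lower in both anti-SIGLEC15 libraries. Vegfa, the vascular endothelial growth factor gene, measured 134 RPKM in IgG replicate 1, 25.2 RPKM in IgG replicate 2, and 45.6 and 38.7 RPKM in the anti-SIGLEC15 libraries, and without IgG replicate 1 the median of the hypoxia list was 0.11. These glycolysis and hypoxia genes were chosen after their values were seen.

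The red cell and platelet list fell by a median of -3.58 (camera, adjusted p = 1.01e-13; adjusted p = 0.498 with an estimated correlation), with 5 of 7 tested members lower in both anti-SIGLEC15 libraries. These were the 4 haemoglobin genes Hba-a1, Hba-a2, Hbb-bs and Hbb-bt and Alas2, which encodes the first enzyme of haem synthesis in red cells, and all 5 passed when adjusted over the list alone. The platelet genes Ppbp and Pf4 did not pass. The adjusted p of this list ran from 2.99e-143 to 0.622 over the alternatives, and its median stayed negative without IgG replicate 1 (-4.58) and without IgG replicate 2 (-2.58). Natural killer cell genes rose by a median of 0.58 (adjusted p = 0.0133; adjusted p = 0.691 with an estimated correlation). A single member, the receptor gene Klra7, lay higher in both anti-SIGLEC15 libraries, with 0.493 and 1.43 RPKM in the IgG libraries and 2.62 and 32.5 RPKM in the anti-SIGLEC15 libraries. Without anti-SIGLEC15 replicate 2 the median of the natural killer list was 0.19 and its call ended, as it did with a filter at 5 RPKM.

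**Figure D3:**
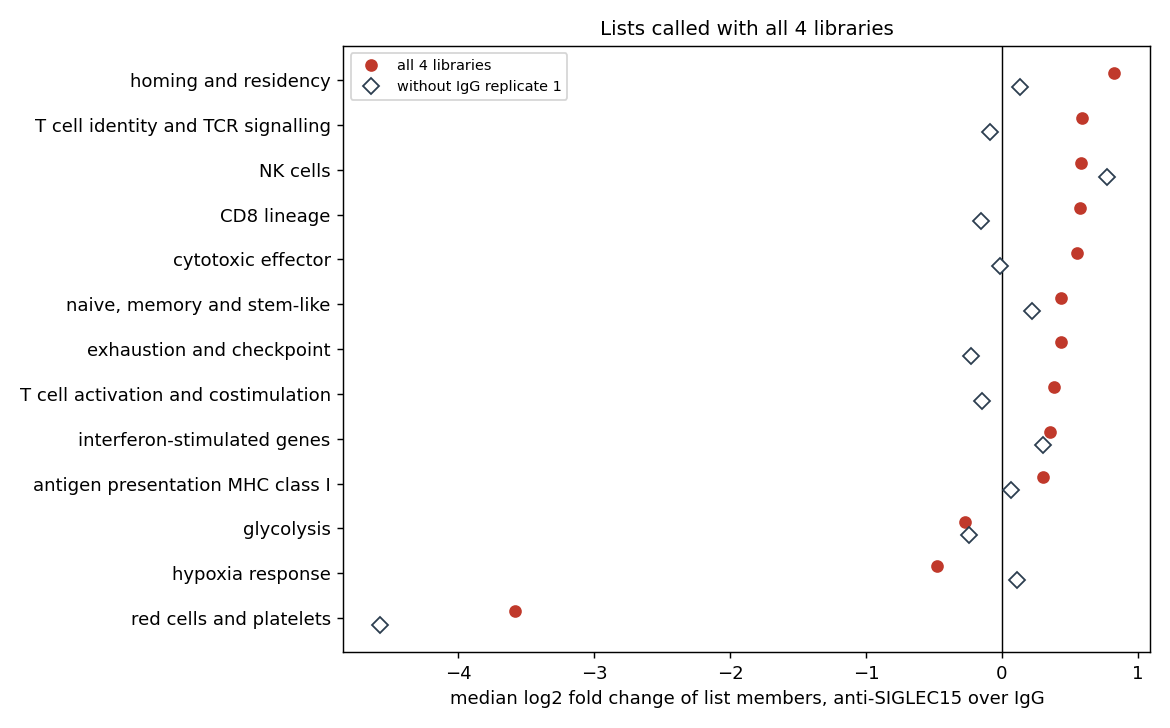
Median log2 fold change of anti-SIGLEC15 over IgG for the 13 lists called in camera, with all 4 libraries (red circles) and without IgG replicate 1 (open diamonds). The medians of the T cell identity, CD8 lineage, exhaustion, activation, cytotoxic and hypoxia lists crossed 0 without IgG replicate 1, and those of the glycolysis (-0.27 and -0.24), interferon (0.36 and 0.31) and red cell (-3.58 and -4.58) lists did not.

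In total, camera called 10 lists raised and 3 lowered among 25 tested, and 0 of each with an estimated correlation or with fry. With 2 libraries per group, the test with an estimated correlation also has few degrees of freedom. A lost call therefore does not show that correlation between genes explains it. The camera p of the glycolysis list, with an estimated correlation of -0.02, went from 7.02e-06 to 0.0398. Other splits of the 4 libraries called 13 and 12 lists at the preset correlation. Among the 12 lists that did not pass were cell cycle (median 0.12, adjusted p = 0.208), nuclear genes of oxidative phosphorylation (-0.04, adjusted p = 0.431), mitochondrially encoded genes (0.04, adjusted p = 0.819), CD4 and regulatory T cells (0.21, adjusted p = 0.361), dendritic cells (-0.47, adjusted p = 0.305), macrophages and monocytes (0.09, adjusted p = 0.731), TGF-beta response (0.26, adjusted p = 0.315), apoptosis and p53 (0.07, adjusted p = 0.741), and immediate early genes (-0.02 with an upward test, adjusted p = 0.731). When the libraries were scaled to the T cell identity genes, the median of all genes moved from 0.02 to -0.55, and the medians of the exhaustion (-0.18), interferon (-0.23), MHC class I (-0.35), natural killer (-0.11), naive and memory (-0.10), activation (-0.10), cytotoxic (-0.11), CD8 lineage (-0.08) and T cell identity (-0.04) lists lay below 0 but above that of all genes. Under this scaling the median of the homing list was 0.25, and those of the glycolysis (-0.92), hypoxia (-1.11) and red cell (-4.19) lists lay below that of all genes.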

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

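The covariate fit, array weights and the restriction to protein-coding genes were chosen after seeing the data. The count of 0 changed genes held under every scaling and filter, the smaller pseudocount, limma-voom, the test against a 1.5-fold change, array weights, protein-coding genes and the replicate block. Planned fits with count models were not run, because the plan set the fallback for files of normalized values. The recovered reads were fitted with limma-voom only. With the T cell level as covariate, 120 genes were called, 83 higher and 37 lower, 117 of them by at least 2-fold. With a library left out, the counts ran from 0 to 2129 for changed, 0 to 961 for raised, 0 to 1168 for lowered and 0 to 1959 for 2-fold changed genes; fewer libraries leave a single IgG pool as the reference in the fits with the most calls. The 10 lists raised and 3 lowered became 0 and 0 with an estimated correlation and with fry. Lists lowered numbered 6 at a filter of 5 RPKM and 4 to 7 with a library left out. The labels do not say whether equal replicate numbers mark a shared batch or day, and with 2 pairs this stays unknown: deviations of the libraries numbered 1 correlated at 0.33, and with the replicate block 0 genes passed, 303 at an unadjusted p under 0.05. For the lists, the block gave 10 raised and 4 lowered, the hepatocyte list being added.

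Scaling to the T cell list moved the median of all genes from 0.02 to -0.55, and the sign changes under it follow from that construction, which lowers nearly all log2 fold changes alike. Among the named genes they were Cd3e -0.04, Cd8a -0.08, Mki67 -0.2, Tox -0.22, Pdcd1 -0.26, Gzmb -0.36 and Tcf7 -0.58, and every list median above 0 except that of the homing list fell below 0. The direction of the test turned only for apoptosis (median -0.58) and neutrophils (-0.53). The T cell covariate was the mean level of the T cell identity genes themselves, so the values of that list under it lie near 0 by construction. That level was 24.7 in IgG replicate 1, 69.3 in IgG replicate 2 and 64.7 in each anti-SIGLEC15 library. The covariate therefore mainly set IgG replicate 1 apart, and its fit is no independent check beside leaving that library out. The cause of the other reversals that follow was not tested. With the T cell covariate, log2 fold changes were Gzmb -0.01, Cd3e -0.11, Cd8a -0.11, Pdcd1 -0.24 and Tox -0.38, and for lists T cell identity -0.01, activation -0.04, cell cycle -0.06, CD4 and regulatory T cells -0.07, exhaustion -0.11, cytotoxic 0.04 with a downward test, hepatocytes 0.4, dendritic cells 0.43, epithelial cells 0.54 and neutrophils 1.27. The test also turned for CD4 and regulatory T cells at 5 RPKM (0.08), dendritic cells with no filter (0.14), and, with shared members removed, cytotoxic genes (0.35) and macrophages (0.08).

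With each library left out in turn, log2 fold changes ran from -0.21 to 1.4 for Cd3e, -0.22 to 1.39 for Cd8a, -0.06 to 0.68 for Gzmb, -0.34 to 1.14 for Pdcd1, -0.95 to 0.49 for Prf1, -0.6 to 0.76 for Tcf7 and -0.5 to 1.3 for Tox. List medians ran from -0.16 to 0.65 for CD4 and regulatory T cells, -0.16 to 1.41 for the CD8 lineage, -0.15 to 1.09 for activation, -0.09 to 1.42 for T cell identity, 0.05 to 0.37 for TGF-beta response, -0.02 to 0.15 for apoptosis, -0.17 to 0.46 for cell cycle, -0.02 to 1.09 for cytotoxic genes, -1.43 to 0.6 for dendritic cells, -1.61 to 0.68 for epithelial cells, -0.23 to 1.21 for exhaustion, -1.16 to 0.53 for hepatocytes, -1.11 to 0.11 for hypoxia, -0.69 to 0.68 for immediate early genes, -0.37 to 0.25 for macrophages, -0.42 to 0.46 for mitochondrially encoded genes and -1.06 to 1.46 for neutrophils.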

Other observations

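The tests of explanations in this part were set up after the results they bear on had been seen, although leaving out IgG replicate 1 and the T cell list levels had been planned. T cell receptor V segments differed widely between the 4 pools. Trbv15 took 75.2% of TRBV reads in anti-SIGLEC15 replicate 2 (Wilson 95% interval 74.0 to 76.3%), 53.7% in anti-SIGLEC15 replicate 1 (52.2 to 55.2%) and 30.8% in IgG replicate 2 (29.6 to 32.0%), where Trbv12-2 led with 36.0%. In IgG replicate 1, Trbv1 led with 45.3% of 1387 TRBV reads (42.7 to 47.9%). Among TRAV segments, Trav12-2 led in both anti-SIGLEC15 libraries, with 47.0% and 59.0%, against Trav13-1 with 29.5% in IgG replicate 2 and Trav6d-4 with 36.3% in IgG replicate 1. Trav12-2 itself took 23.4% in IgG replicate 2 and 12.0% in IgG replicate 1. The effective number of TRBV segments was 3.7 and 4.2 in the IgG libraries and 3.2 and 1.7 in the anti-SIGLEC15 libraries. The intervals cover counting error only, and V segments are alike enough to share reads. Of the 125 genes called without IgG replicate 1, 38 were receptor or immunoglobulin segments, and 42 of the 125 also had both anti-SIGLEC15 libraries on the same side of IgG replicate 1.

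Igkc, an immunoglobulin light chain gene, measured 17.8 and 47.4 RPKM in the IgG libraries and 82.3 and 107.7 RPKM in the anti-SIGLEC15 libraries, and the heavy chain gene Ighm 6.85, 20.4, 28.7 and 26.2 RPKM. Both were picked after their values were seen and were not tested as a group. The list of B and plasma cell genes had 3 tested members, too few for a test.

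T cell and CD8 genes were higher with anti-SIGLEC15 as lists, calls that were lost with an estimated correlation in camera (adjusted p = 0.691 for each). The list levels showed no rise above both IgG pools. The T cell identity level was 64.7 in each anti-SIGLEC15 library against 69.3 in IgG replicate 2. For the CD8 lineage it was 193 and 203 against 203. Of the 35 members, 17.1% lay higher in both anti-SIGLEC15 libraries (13.0% for T cell identity, 25% for the CD8 lineage). Chance gives 16.7%, and the share over all tested genes was 12.1%. More tumour RNA in IgG replicate 1 is a candidate explanation of the list calls, since the T cell median was -0.09 without that library. The epithelial and hepatocyte list levels of IgG replicate 1 (geometric means of RPKM + 1, less 1) were 59.9 and 72.5. They were 17.6 and 23.6 in IgG replicate 2 (Alb 2795 and 556 RPKM). CD8 enrichment is meant to remove tumour cells, but hepatocyte transcripts remained in every library. The neutrophil level of IgG replicate 1 was higher too (32.1 against 4.97), so this explanation stays open. Anti-SIGLEC15 replicate 1 had a hepatocyte level of 60.6, close to that of IgG replicate 1, with an epithelial level of 29.6 and Alb at 1089 RPKM. Its T cell level of 64.7 was close to the 69.3 of IgG replicate 2. The 12 abundant hepatocyte members (mean of at least 5 RPKM) were a median of 4.13-fold higher in IgG replicate 1 than in IgG replicate 2. In anti-SIGLEC15 replicate 1 that median was 2.33-fold. The hepatocyte level alone therefore does not settle whether tumour RNA tracks the T cell level. Of the 3 splits of the 4 libraries, the real one called 13 lists, the split by replicate number 13 and the remaining split 12. The number of lists called therefore does not set the treatment apart from other groupings, and 3 splits are too few for a share under 0.05. Genes at an unadjusted p under 0.05 in limma numbered 146 in the real split, 318 in another and 1446 in the split by replicate number. In each split 0 genes passed after adjustment. The real split thus had the fewest genes at an unadjusted p under 0.05, and the cause of this order was not tested. An effect of the treatment on the T cell share of a pool stays open, as each group has 2 pools.

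Granzymes C to G were lower in both anti-SIGLEC15 libraries. Against fewer T cells there, the T cell identity level of the lower anti-SIGLEC15 library differed from that of the higher IgG library by -0.1 on the log2 scale, far less than the granzymes. Reads exchanged between these close relatives would leave their sum alike, but it differed by -1.36 on the log2 scale, from 450.9 and 621.3 RPM with IgG to 230.8 and 184.5 RPM with anti-SIGLEC15. An exchange with the far more abundant Gzmb cannot be told apart. The sum with Gzmb was 1599.4 and 2537.3 RPM with IgG and 2347.1 and 1785.6 RPM with anti-SIGLEC15. Its difference of 0.02 says little, since Gzmb makes up most of this sum and overlapped between the groups. A lower expression of this cluster after SIGLEC15 blockade stays open as a hypothesis, from 2 pools against 2 in which no gene passed the test over all genes.

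Haemoglobin transcripts were lower in both anti-SIGLEC15 libraries, by a factor of at least 3.25 between the closest libraries of the 2 groups for each of the 4 globin genes and Alas2. Red cell RNA carried into each pool in a fixed proportion is a candidate explanation. CD8 enrichment is meant to remove red cells, but haemoglobin transcripts remained in every library. The log2 ratios of these 5 genes had an SD of 0.76 for anti-SIGLEC15 replicate 2 over IgG replicate 1. For the other pairs of libraries the SD lay between 0.26 and 0.59. From IgG replicate 1 to anti-SIGLEC15 replicate 2, Alas2 went from 1.35 to 0.056 RPKM, a value near the floor. The largest SD does not rest on it, since its ratio lay between those of Hba-a2 and Hbb-bt. Between the same libraries Hba-a2 went from 51.3 to 3.53 RPKM and Hbb-bt from 32.3 to 0.575 RPKM. The SDs neither count for this explanation nor exclude it. A treatment effect on blood content cannot be told apart from a difference between pools, since the ratio of 3.25 comes from 2 pools per group. The anti-SIGLEC15 pools also differed from each other, with Hbb-bs at 53.7 and 9.55 RPKM.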
